A study of Homo sapiens with 9 samples.

How the data were processed

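ATAC-seq libraries of human T cells were analysed from the peak lists that the authors deposited, one list per library and no pooled list. Per the labels, cells were frozen and shipped to a sequencing provider. Peaks were called with MACS3 3.0.1 on GRCh38, per the submitters' processing notes. The aligner, read filters, transposase shift and caller settings are not given in the sources used here, and any of them could change the number and width of peaks. Each deposited list gives, per summit, a fold enrichment (a ratio to the caller's local background), −log10 p and −log10 q values, a score that is 10 times −log10 q on nearly all lines, and the offset of the summit. The lowest deposited −log10 q was 2.00 in each library. These values are the authors' and describe peaks within a library; they were used to rank and filter peaks, and folds are quoted as descriptions.

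Where several summits shared an interval, the summit with the highest −log10 p was kept. Chromosomes 1 to 22 and X were used. The lists give no read totals, so the depth was approached through the peak statistics: for summits with −log10 p under 300, the whole read coverage and the local background that give the deposited fold and p were solved, and 100% of summits gave a whole coverage within 0.001 of the deposited −log10 p. The most common background of a library, from 1.20 in Tex DMSO 1 to 2.27 in Tex Mezi 2, was taken as a measure that scales with depth; the median coverage at summits ran from 19 reads to 29 reads. No pair of libraries shared more than 0.185% of intervals with identical coordinates.

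Peak numbers differ between libraries, so each list was reduced to its 12828 peaks with the highest −log10 p. Intervals of all libraries that shared at least 1 bp were merged into regions, and a region was called in a library that had a peak in it. For each pair of groups, regions called in 3 of 3 libraries of one and 0 of 3 of the other were counted, and searched again in the full lists. With 3 against 3, no single region can pass a test (smallest two-sided exact p 0.1), so counts were set against the other splits of the same 6 libraries. Similarity was the Jaccard index. Values per library were tested by exact permutation over all labellings (smallest p 0.00357 over 3 groups). Adjusted p-values are Benjamini-Hochberg. The tests of peak numbers, covered length and background, the shares in libraries left out, the mean similarity of Tex libraries to Tact DMSO, the calls in the third group, and the Fisher tests of gene lists were added after seeing the data. Intervals of shares are 95% Wilson intervals and cover counting error of regions only.

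Genes came from a RefSeq table of GRCh38 with 19970 protein-coding genes on these chromosomes. It gives no strand, so start sites were not known and either boundary of a gene span was used in their place, chosen after seeing the data; a region near a boundary can therefore lie at the end of a gene, and exons and introns were not told apart. A peak or region was assigned to the gene whose span, widened by 5 kb, holds its midpoint, or else to the nearest boundary within 100 kb. The 18 gene lists, with 358 genes, all found in the table, were written before the data were examined, as were the tests, the groups and the rule for named genes. That rule took, per comparison and direction, regions of one group alone in both equal-length and full lists: the 6 with the best mean rank, 1 per gene, and up to 10 at genes of the lists, together with PDCD1, HAVCR2, TOX, IFNG, IL2, TCF7, IKZF1 and IKZF3. List genes outside this rule are named as such, by their place in equal-length lists alone, and were chosen after their values were seen. Some list genes are not reported here by name. A planned comparison of 21 transcription factor motifs needs the genome sequence, which was not used here, and was not run.

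The method was tested on simulated calls on 69606 regions with 200 planted changes for a comparison of 3 with 3 libraries. It recovered 13.0% of regions shifted by 1 on the log2 rank scale, 54.5% at 2 and 79.5% at 4, with 0 in the wrong direction, and called 202 to 207 unplanted regions. The simulated spread came from regions called in all Tact DMSO and all Tex Mezi libraries, and changes were planted at middle ranks of the equal-length lists. Recovery with the spread of Tex DMSO was not simulated. Alternatives were the full lists, ranking by fold, a −log10 q of at least 5 in full lists, windows of 501 bp around summits, leaving out chromosome X, each library or the distinction of replicate numbers, a limit of 3 kb and other gene assignments. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.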

Results

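Chromatin accessibility was profiled by ATAC-seq, in which a transposase inserts sequencing adapters into open DNA. The samples were human T cells in 3 groups of 3 libraries, named Tact DMSO, Tex DMSO and Tex Mezi in the labels. The series concerns T cell exhaustion and mezigdomide (Mezi), a cereblon-binding drug that leads to degradation of the transcription factors Ikaros (IKZF1) and Aiolos (IKZF3); DMSO is its solvent. The labels give a cell line as the source, without naming it, and do not define Tact and Tex. They do not say whether the 3 libraries of a group came from separate donors or cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

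Tex DMSO libraries had the shortest peak lists. On chromosomes 1 to 22 and X, Tact DMSO had 40389 ± 9349 peaks, Tex DMSO 19240 ± 6377 and Tex Mezi 30144 ± 905 (SD, n = 3 each). The 3 groups did not overlap in number (exact permutation test, two-sided, p = 0.00357, the smallest that 1680 labellings can give). Each pair of groups gave an exact two-sided p of 0.1, the smallest possible with 3 against 3. Peaks covered 13.8 ± 2.66 Mb in Tact DMSO, 6.86 ± 2.97 Mb in Tex DMSO and 11.95 ± 0.212 Mb in Tex Mezi (SD, n = 3 each; exact permutation p = 0.0143). The background read coverage recovered from the peak statistics, which scales with sequencing depth, was 1.35 ± 0.113, 1.46 ± 0.248 and 1.79 ± 0.433 in the same order (SD, n = 3 each; exact permutation p = 0.236). Because the numbers were unequal, regions were compared on the 12828 peaks with the highest deposited −log10 p of each library, the length of the shortest list (Tex DMSO 3).

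**Figure D1:**
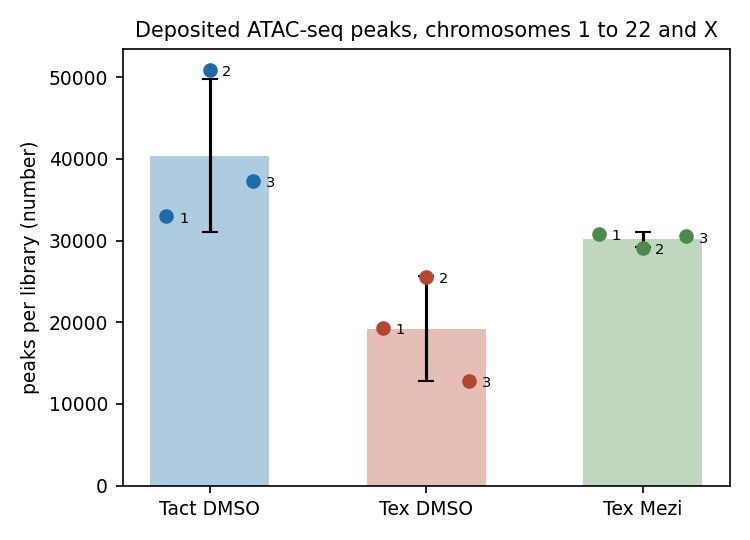
Number of deposited ATAC-seq peaks on chromosomes 1 to 22 and X (vertical axis) in each library of the 3 groups. Points are libraries with their replicate numbers, bars are group means and error bars are SD (n = 3); the Tex DMSO libraries lie between 12828 and 25582, below all libraries of both other groups.

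The equal-length lists gave 23938 merged regions, of which 6067 were called in all 9 libraries and 5859 in 1 library. Of the 6067 shared regions, 73.6% lay within 1 kb of the boundary of a protein-coding gene, compared with 37.7% of all regions. The Jaccard index in base pairs was 0.0801 higher on average within than between groups (exact permutation test, one-sided, p = 0.00357, the smallest of 280 partitions). Within groups it was 0.580 ± 0.0331 in Tact DMSO, 0.493 ± 0.0508 in Tex DMSO and 0.625 ± 0.0113 in Tex Mezi (SD over 3 pairs each). Between groups it was 0.496 ± 0.0773 for Tex DMSO with Tex Mezi, 0.469 ± 0.0576 for Tact DMSO with Tex DMSO and 0.492 ± 0.0193 for Tact DMSO with Tex Mezi (SD over 9 pairs each). Tex DMSO libraries were thus no more alike among themselves than with Tex Mezi in base pairs. Counted in windows of fixed width around summits, the index was 0.634 ± 0.0266 within Tact DMSO, 0.585 ± 0.0455 within Tex DMSO and 0.659 ± 0.0145 within Tex Mezi (SD over 3 pairs each). For Tex DMSO with Tex Mezi it was 0.579 ± 0.0321, for Tact DMSO with Tex DMSO 0.535 ± 0.0316 and for Tact DMSO with Tex Mezi 0.515 ± 0.0128 (SD over 9 pairs each). No difference between Tex DMSO and Tex Mezi libraries in mean similarity to Tact DMSO passed by either measure (exact permutation, two-sided, p = 0.7 in base pairs and 0.4 in windows, both added after seeing the data), and the order of their means turned between the measures.

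**Figure D2:**
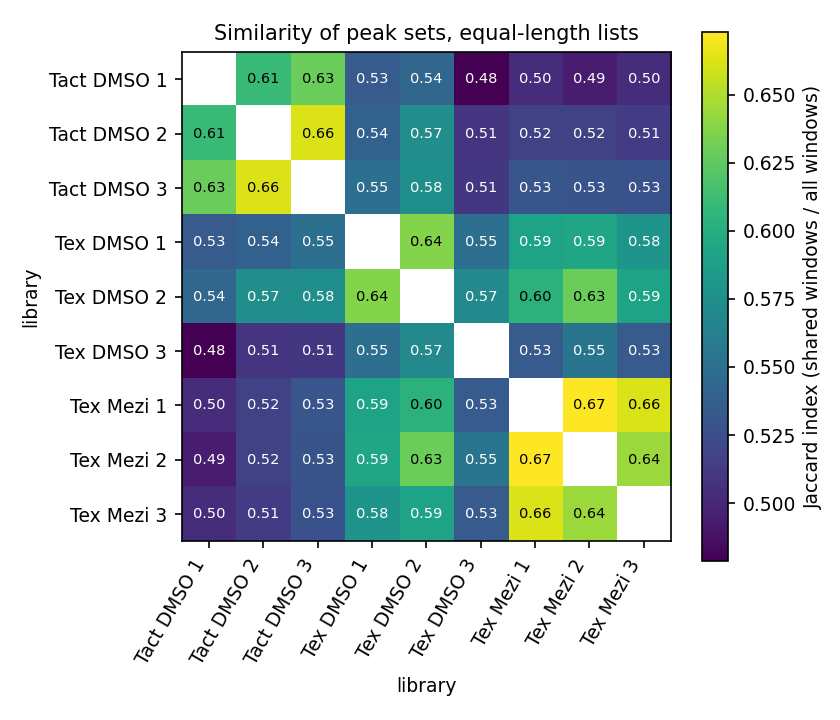
Jaccard index of each pair of libraries, as windows called in both over windows called in either, from equal-length lists. Both axes list the 9 libraries and colour gives the index; the mean over pairs was 0.515 for Tact DMSO with Tex Mezi and 0.659 within Tex Mezi.

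The first comparison set Tex against Tact cells without the drug. KLF7, a Krüppel-like transcription factor, had a region called in all Tact DMSO libraries and in no Tex DMSO library, also when all deposited peaks were searched (chromosome 2, 207123415 to 207123784, inside the gene, fold enrichment over background 13.2 ± 2.45, SD, n = 3). The same held for IL12RB2, a cytokine receptor chain (chromosome 1, 67400036 to 67400578, 1.6 kb outside the gene, 9.48 ± 1.02), and CDK6, a cell cycle kinase (chromosome 7, 92768874 to 92769286, inside the gene, 9.74 ± 1.35). It also held for TNFRSF8, a receptor of activated lymphocytes (chromosome 1, 12067960 to 12068382, inside the gene, 7.97 ± 1.43). In the other direction such regions lay inside ARAP2 and SORCS1 and nearest to PSEN2, ZBTB44, MYRFL and P2RY1, genes outside the fixed lists. The SORCS1 region was not fully separated when a −log10 q of at least 5 was required. Folds are the authors' values, given as mean ± SD over the 3 libraries of the group that has the peak.

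In number, 647 regions were called in 3 of 3 Tact DMSO and 0 of 3 Tex DMSO libraries, and 393 the other way. A search of all deposited peaks is stricter for Tex DMSO regions, because the full Tact DMSO lists are longer than every Tex DMSO list. For Tex DMSO 3 the full list is the equal-length list. The search therefore does not compare the directions. By it, 261 of the 647 and 11 of the 393 were absent from the other group. Under alternatives added after seeing the data, these counts were 452 and 14 when ranked by fold, up to 578 and 25 on leaving out 1 library, and 1048 of 1432 and 116 of 1105 without Tex DMSO 3 at the next shortest length. The other Tact DMSO regions with the best ranks lay 3.7 kb from ATG16L1, an autophagy gene (fold 10.9 ± 4.50), inside RNPC3, SLC22A2 and RHBDD1, and 1 kb from FNIP1 (SD, n = 3). OASL, an interferon-induced gene, and BANK1, listed as a B cell marker, also had regions among the 261 (7.16 ± 1.36 and 11.1 ± 0.845, SD, n = 3), of which the OASL region was not fully separated when peaks were ranked by fold. The KLF7 and CDK6 regions were each called in 3 of 3 full Tex Mezi lists, and the IL12RB2 and TNFRSF8 regions in 1. The regions at ATG16L1, SLC22A2, RHBDD1 and FNIP1 were each called in 0 full Tex Mezi lists, and those at RNPC3, OASL and BANK1 in 1. Those lists are longer than every Tex DMSO list. At equal length the CDK6 region was called in 1 Tex Mezi library, and the KLF7, IL12RB2 and TNFRSF8 regions in 0.

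Further list genes among the 647 had a peak of lower rank in at least 1 full Tex DMSO list. They were REL, DUSP2, IL1R1, BACH2, PRDM1, MYB, IKZF1, SRGN, VSIR, KLRG1, LAT, STAT3, CD226, KLF2 and NFATC2. Naive, memory and stem-like genes had 4 of 21 members among the 647 (BACH2, KLF2, KLF7 and MYB), and cytokine receptor and JAK-STAT genes 3 of 31 (IL12RB2, IL1R1 and STAT3). Neither list was enriched (Fisher's exact test, adjusted p = 0.780 and 0.649 over 108 tests). Among the 393 regions of Tex DMSO, list genes were CDKN2C, JAK1, RSAD2, BACH2, FYN, PRKCQ, DGKA, MAF, JUNB and IL2RB. All of these regions were called in at least 1 full Tact DMSO list.

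**Figure D3:**
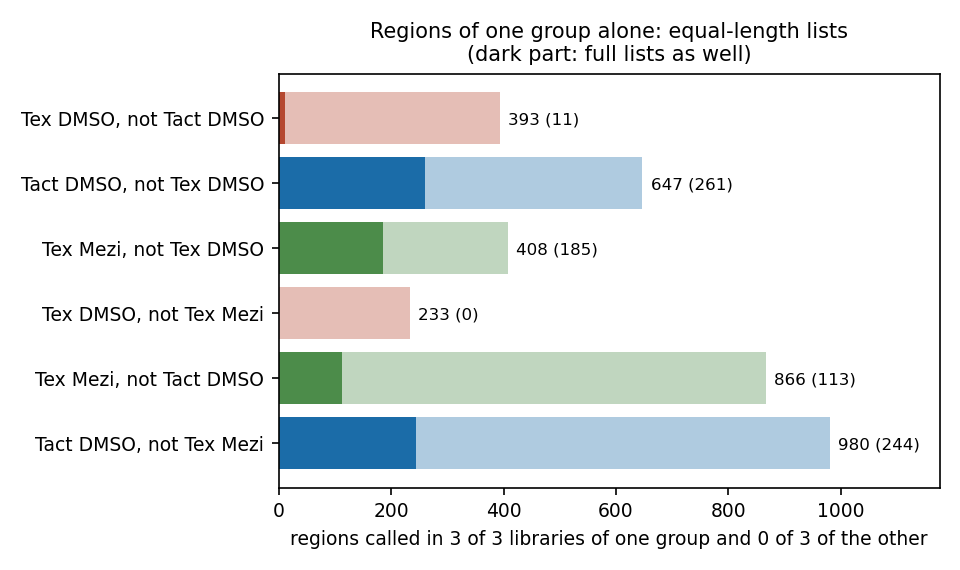
Regions called in 3 of 3 libraries of one group and 0 of 3 of the other (horizontal axis, number of regions) for each ordered pair of groups. Whole bars are equal-length lists, and dark parts, with the number in parentheses, are regions that the full lists place in one group alone as well; Tex DMSO regions missing in Tex Mezi number 233, of which 0 are absent from all full Tex Mezi lists.

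The second comparison addressed mezigdomide in Tex cells. Regions called in all Tex Mezi libraries and in no Tex DMSO library, in the full lists as well, lay inside STAT4, a signal transducer of cytokine receptors (chromosome 2, 191109959 to 191110399, fold 10.8 ± 2.85, SD, n = 3), and ICOS, a costimulatory receptor (chromosome 2, 203951127 to 203951856, 8.33 ± 0.879). Others lay inside PAG1, an adaptor that restrains T cell receptor signalling (chromosome 8, 81026424 to 81026785, 8.97 ± 1.21), and LEF1, a transcription factor of naive T cells (chromosome 4, 108155447 to 108155686, 7.45 ± 1.40). S1PR1, a receptor for egress from lymphoid tissue, had one 49.6 kb from the gene (chromosome 1, 101291776 to 101291976, 5.52 ± 0.817), which was not fully separated when peaks were ranked by fold.

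There were 408 regions called in 3 of 3 Tex Mezi and 0 of 3 Tex DMSO libraries, of which 185 also held in the full lists. The other way there were 233, of which 0 held. Under the same alternatives 296 and 4 held when ranked by fold, up to 378 and 11 on leaving out 1 library, and 810 of 1086 and 135 of 671 without Tex DMSO 3 at the next shortest length. The other Tex Mezi regions with the best ranks lay at TMC1 (fold 8.17 ± 0.756), CHN1 (9.14 ± 2.31) and LSMEM1 (8.998 ± 1.14; SD, n = 3). A pair of regions near POMZP3 (16.7 ± 2.32) and inside SRGAP2 (14.8 ± 2.10) is uncertain, since both genes have near-identical copies elsewhere in the genome. List genes with Tex Mezi regions that some full Tex DMSO list held were S1PR1 (a further region), CBLB, EBF1, GATA3, CD69 and BACH1.

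The 233 Tex DMSO regions included HAVCR2, an inhibitory receptor (chromosome 5, 157109006 to 157109406, fold 5.49 ± 0.482, SD, n = 3), and IFNG, the gene of interferon gamma (chromosome 12, 68175597 to 68176089, 5.79 ± 1.56). Other list genes included IL12RB2, JAK1, SOCS3, STAT6, BACH2, KLF7, FYN, PTPN6, CDK6 and RAB7A. All 233 were called in at least 1 full Tex Mezi list and 183 in all 3, but the full Tex Mezi lists are longer than every Tex DMSO list. No fixed list was enriched among the 408 or the 233. The lowest adjusted p was 0.212, for cytokine receptor and JAK-STAT genes among the 233 (4 of 31 genes, Fisher's exact test).

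Regions chosen without 1 library of each group were then looked up in the libraries left out, a test added after seeing the data. Tex Mezi regions missing in Tex DMSO were called in 64.9% of cases in the Tex Mezi library left out and in 28.0% in the Tex DMSO library left out (exact permutation over 20 labellings, one-sided, p = 0.05, the smallest possible). Tex DMSO regions missing in Tex Mezi gave 54.1% and 28.2% (exact permutation p = 0.1). The shares were 67.4% and 21.5% for Tact DMSO regions missing in Tex DMSO (exact permutation p = 0.05) and 60.3% and 26.7% the other way (exact permutation p = 0.1). They were 71.2% and 12.8% for Tact DMSO regions missing in Tex Mezi (exact permutation p = 0.05) and 71.1% and 18.7% the other way (exact permutation p = 0.1). Exchanging the labels gives the opposite direction, so the direction with the smaller difference in each pair of groups cannot go below 0.1.

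The third comparison set treated Tex cells against Tact cells. The label (Tex or Tact) and the drug both differ in this pair, so their parts cannot be told apart in it. Tact DMSO regions absent from Tex Mezi, in the full lists as well, lay 25 kb from CD28, the main costimulatory receptor (chromosome 2, 203763542 to 203764287, fold 10.5 ± 1.79, SD, n = 3), and 8.8 kb from REL, an NF-kappaB subunit (chromosome 2, 60872513 to 60873072, 12.4 ± 5.02). IL1R1, a cytokine receptor, had one inside the gene (chromosome 2, 102137055 to 102137458, 11.6 ± 5.29) and one 7.9 kb outside (102062224 to 102062802, 8.21 ± 2.51). Tex Mezi regions absent from Tact DMSO lay 15.6 kb from IL10RA, a cytokine receptor (chromosome 11, 117970561 to 117971083, 7.39 ± 0.429), inside CBLB, a ubiquitin ligase that limits T cell activation (chromosome 3, 105828030 to 105828270, 6.09 ± 1.44), and inside IKZF1 (chromosome 7, 50308465 to 50309108, 5.24 ± 1.07). IKZF1 also had a region of the opposite kind at equal length, called in all Tact DMSO and no Tex Mezi libraries (50317225 to 50317915, 8.60 ± 2.22).

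This pair of groups had 980 regions of Tact DMSO alone (244 in the full lists as well) and 866 of Tex Mezi alone (113 in the full lists as well). At equal length, 510 of the 980 were called in 0 and 80 in 3 Tex DMSO libraries. Of the 866, 298 were called in 0 and 173 in 3 Tex DMSO libraries. The full Tact DMSO lists are longer than every full Tex Mezi list, so this search was stricter for Tex Mezi regions. Under the same alternatives 394 and 199 held in the full lists when ranked by fold, up to 406 and 215 on leaving out 1 library, and 837 of 1564 and 432 of 1517 without Tex DMSO 3 at the next shortest length. RORA, a nuclear receptor, and SRGN, a proteoglycan of cytotoxic granules, were further list genes among the 244 (folds 9.40 ± 2.83 and 6.49 ± 1.48, SD, n = 3). Ranked by fold, the IKZF1 region of Tex Mezi and the SRGN region no longer separated the groups, and the CBLB region and the IL1R1 region outside the gene did so in part. Other best-ranked regions lay at ACTR3, ATG16L1, MED30, MGAT5 and PCYT1B for Tact DMSO and at SLC9A9, LRBA, CHN1, LSMEM1, EDNRA and RNPC3 for Tex Mezi.

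Naive, memory and stem-like genes were enriched among the 980 regions by a test that counts regions of the same gene as independent. Of the list's 21 genes, 7 held 10 regions (BACH2, CD28, FOXP1, KLF2, KLF7 and MYB among them), of 23 regions of the list called in all Tact DMSO libraries (Fisher's exact test, p = 6.95e-05, adjusted p = 0.00751 over 108 tests, chosen after seeing the data). Among regions over 1 kb from a gene boundary alone, the odds ratio was 2.57 and the enrichment did not pass (Fisher's exact test, p = 0.0424, adjusted p = 1). The same list held 7 regions of 4 genes (BACH2, FOXO1, LEF1 and S1PR1) among the 866 of Tex Mezi (Fisher's exact test, adjusted p = 0.0568). List regions thus lay in both directions. In peaks per library the list did not differ between the 3 groups (exact permutation test, p = 0.0643, adjusted p = 0.186).

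**Figure D4:**
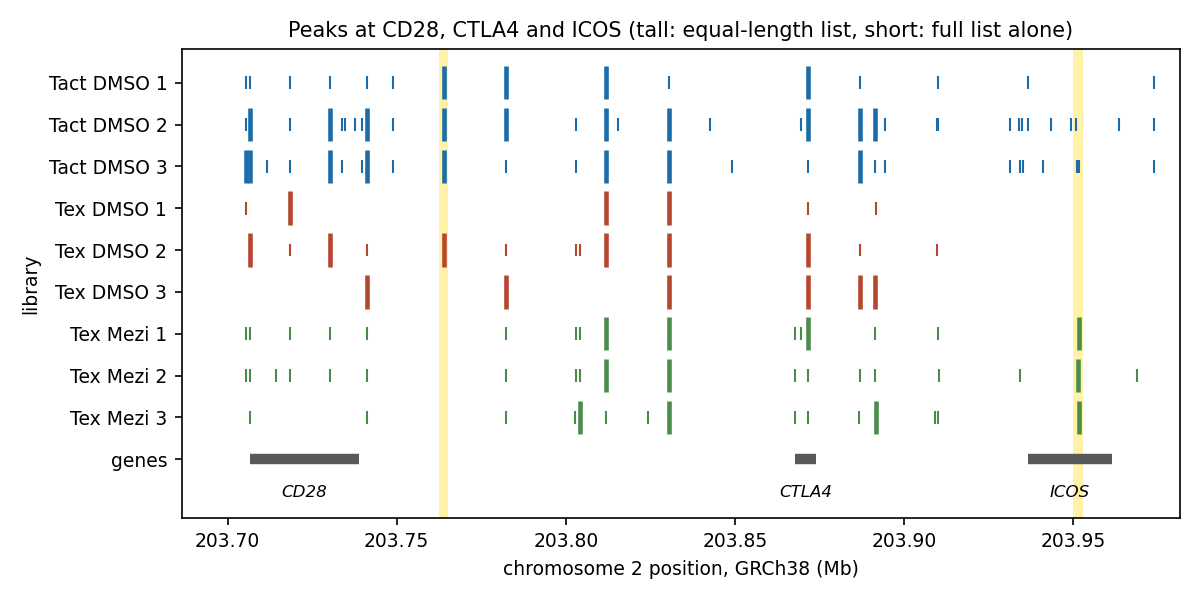
Map of deposited peaks across CD28, CTLA4 and ICOS on chromosome 2 (GRCh38, horizontal axis in Mb) in the 9 libraries, with each mark at the midpoint of a peak; tall marks belong to the equal-length lists and short marks to the full lists alone. Yellow bands, widened for visibility, hold the CD28 region of Tact DMSO (from 203763542) and the ICOS region of Tex Mezi (from 203951127), and the locus was chosen after seeing the data.

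Whether treated Tex cells carried Tact DMSO regions was tested against an untreated library kept out of the selection. Regions called in all 3 Tact DMSO libraries and in neither of 2 Tex DMSO libraries were taken. The held-out Tex DMSO library held 23.5% ± 0.545 of them and Tex Mezi libraries 17.9% ± 2.22 (SD, n = 3 each). The difference of -5.60 percentage points did not pass the threshold (exact permutation over 20 labellings, two-sided, p = 0.15). It was 13.4 with all deposited peaks (exact permutation p = 0.05), where the Tex Mezi lists are longer than those of Tex DMSO. Of the 647 Tact DMSO regions missing in Tex DMSO, 510 were called in 0 and 25 in 3 Tex Mezi libraries. Of the 393 Tex DMSO regions missing in Tact DMSO, 173 were called in 3 and 60 in 0.

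**Figure D5:**
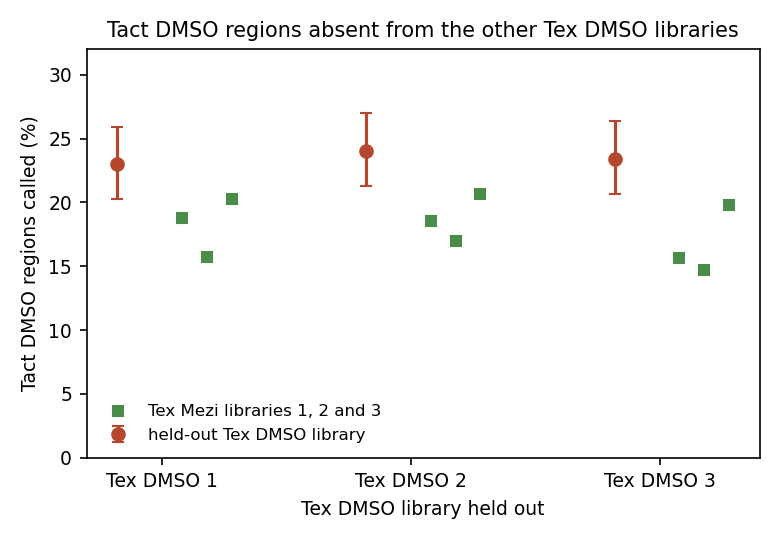
Share of Tact DMSO regions (vertical axis, %) called in the held-out Tex DMSO library (circles, with the 95% Wilson interval of counting error) and in Tex Mezi libraries 1, 2 and 3 (squares, left to right), for each choice of held-out library. Held-out shares lie between 22.98% and 24.1%, above the Tex Mezi shares, which run from 14.7% to 20.7%.

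Peaks near genes made up a smaller part of the Tact DMSO lists. Within 1 kb of a protein-coding gene boundary lay 49.9% ± 1.30 of the equal-length peaks in Tact DMSO, 55.3% ± 1.63 in Tex DMSO and 55.5% ± 2.53 in Tex Mezi (SD, n = 3; exact permutation over 3 groups, p = 0.0393). Either Tex group against Tact DMSO gave an exact p of 0.1, and Tex Mezi against Tex DMSO an exact p of 1. The test over 3 groups no longer passed without Tact DMSO 1, 2 or 3, Tex DMSO 1 or 2, or Tex Mezi 1 (exact permutation p from 0.0607 to 0.104). The difference between Tex and Tact libraries, 5.53 percentage points, was 12.6 with all deposited peaks and 15.4 with a stricter q. Those lists are uncut and differ in length, so a larger difference there cannot be told apart from list length. Of the 393 regions of Tex DMSO, 40.7% (95% Wilson interval 36.0% to 45.6%) were near a boundary, against 6.03% (4.44% to 8.13%) of the 647 regions of Tact DMSO. The shares were 28.8% (25.8% to 31.9%) and 6.02% (4.70% to 7.69%) for Tex Mezi and Tact DMSO regions of that pair, and 15.4% and 20.6% for Tex Mezi and Tex DMSO. Among regions that held in the full lists, 0 of the 11 of Tex DMSO and 5.36% of the 261 of Tact DMSO were near a boundary. In the other pairs it was 3.78% of the 185 and 4.42% of the 113 of Tex Mezi and 4.92% of the 244 of Tact DMSO.

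None of the 18 fixed gene lists differed between the 3 groups in peaks per library (exact permutation test, Benjamini-Hochberg, lowest adjusted p = 0.186, with 2 lists at an unadjusted p of 0.0357). Values below are for Tact DMSO, Tex DMSO and Tex Mezi in this order. Naive, memory and stem-like genes had 46.7 ± 9.02, 36 ± 4.58 and 33.7 ± 2.08 peaks (SD, n = 3; exact permutation p = 0.0643), and AP-1 and other bZIP factors 28 ± 3, 31 ± 3.61 and 34.3 ± 1.15 (exact permutation p = 0.075). Ikaros family and cereblon pathway genes had 20.3 ± 3.51, 15 ± 1.73 and 14.7 ± 1.53 (exact permutation p = 0.075), and type I interferon response genes 12.3 ± 2.31, 15.3 ± 1.15 and 20.3 ± 4.73 (exact permutation p = 0.0857). Inhibitory receptors and exhaustion regulators had 24.3 ± 2.08, 28.3 ± 2.08 and 25.3 ± 2.08 (exact permutation p = 0.154), and cytokines and chemokines 14.7 ± 4.73, 15 ± 1 and 15.3 ± 1.53 (exact permutation p = 0.986). When peaks were ranked by fold, 3 lists passed, each with an adjusted exact permutation p of 0.0429. They were the naive list with means of 44.3, 35 and 25.3 peaks, the AP-1 list with 17.3, 26.3 and 23, and the Ikaros list with 18.7, 14 and 11.

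The other lists are given as means in the same order. Cell cycle genes had 28.3, 35 and 31.7 peaks (exact permutation p = 0.0929), and ubiquitously expressed control genes 26.7, 31.7 and 30.3 (exact permutation p = 0.0571). T cell receptor signalling genes had 44.3, 44.3 and 43.7 (exact permutation p = 1), cytokine receptor and JAK-STAT genes 38.7, 39.3 and 35.3 (exact permutation p = 0.807), and activation and costimulation genes 33.7, 31 and 31.3 (exact permutation p = 0.857). Cytotoxic effectors had 20, 18.3 and 18.7 (exact permutation p = 0.886). Markers of helper and regulatory T cells had 15.7, 13.3 and 11 (exact permutation p = 0.136), and those of CD8 T cells 7.67, 8.67 and 6.67 (exact permutation p = 0.0786). Markers of NK cells had 3, 4 and 3.33 (exact permutation p = 0.571) and of myeloid cells 2.33, 1.67 and 1 (exact permutation p = 0.214). B cell markers had 7.67, 5.33 and 5.33 peaks, and erythroid, endothelial and fibroblast markers 1, 2.33 and 2.33 (both exact permutation p = 0.0357, adjusted p = 0.186).

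Of the 8 genes fixed beforehand, none passed after adjustment. In the full lists TOX, a transcription factor of exhaustion, had 12.7 ± 2.52, 4 ± 2 and 7.33 ± 2.31 peaks in the same order (SD, n = 3; exact permutation p = 0.0214, adjusted 0.0929). IKZF1 had 15.3 ± 5.03, 6.33 ± 2.52 and 15.7 ± 1.53 (exact permutation p = 0.0464, adjusted 0.0929). IKZF3 had 8 ± 3, 3 ± 1 and 3.33 ± 0.577, and TCF7, a stemness factor, 3.33 ± 2.31, 0.667 ± 0.577 and 0.333 ± 0.577 (both exact permutation p = 0.0357, adjusted 0.0929). The full lists differ in length, and at equal length TOX had 2.33 ± 1.15, 3 ± 1 and 2.33 ± 0.577 peaks (exact permutation p = 0.743). IKZF1 then had 6 ± 1.73, 3.67 ± 0.577 and 5 ± 2 (exact permutation p = 0.304), IKZF3 2.33 ± 0.577, 2 ± 0 and 1.33 ± 1.15 (exact permutation p = 0.75), and TCF7 0, 0.333 ± 0.577 and 0 (exact permutation p = 1). At equal length IFNG had 0.667 ± 0.577, 2.33 ± 0.577 and 1 ± 0 (exact permutation p = 0.0357, adjusted 0.286), and HAVCR2 0.333 ± 0.577, 1.67 ± 0.577 and 1 ± 0 (exact permutation p = 0.0714). IL2 had 1.33 ± 0.577, 0.333 ± 0.577 and 0 (exact permutation p = 0.107), and PDCD1 0, 0.667 ± 0.577 and 0.667 ± 0.577 (exact permutation p = 0.357). In the full lists the order differed: IFNG had 4 ± 1, 2.67 ± 0.577 and 3.67 ± 0.577 (exact permutation p = 0.257) and HAVCR2 2 ± 0, 2 ± 0 and 2.33 ± 1.15 (exact permutation p = 1). IL2 had 4 ± 1, 1.33 ± 1.53 and 2.67 ± 1.53 there (exact permutation p = 0.154), and PDCD1 2.33 ± 2.08, 0.667 ± 0.577 and 2.33 ± 0.577 (exact permutation p = 0.3).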

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

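Regions counted over peak lists depend on how many peaks each list holds, and depth limits which weak regions can be compared. The counts in full lists under alternatives were added after seeing the data. Region counts are given in the order Tex DMSO not Tact DMSO, Tact DMSO not Tex DMSO, Tex Mezi not Tex DMSO, Tex DMSO not Tex Mezi, Tex Mezi not Tact DMSO and Tact DMSO not Tex Mezi; at equal length they were 393, 647, 408, 233, 866 and 980. With all deposited peaks they were 29, 5900, 2483, 24, 1324 and 4522, and with a −log10 q of at least 5 in full lists 12, 4719, 2068, 9, 956 and 3541, following the lengths of the lists. Ranking by fold, fixed windows and leaving out chromosome X kept all 6 within 1.5 times. Of these, the regions that held in full lists (11, 261, 185, 0, 113 and 244) became 14, 452, 296, 4, 199 and 394 when ranked by fold, and with fixed windows 25 and 13 in the first and the fourth place; the cause was not tested. Leaving out 1 library gave 393 to 760, 647 to 1029, 408 to 753, 233 to 489, 866 to 1303 and 980 to 1454 regions, and 11 to 25, 261 to 578, 185 to 378, 0 to 11, 113 to 215 and 244 to 406 in full lists as well; with fewer libraries to satisfy, counts can only grow. In an alternative chosen after seeing the data, without Tex DMSO 3 and at the next shortest length, they were 1105, 1432, 1086, 671, 1517 and 1564 regions, and 116, 1048, 810, 135, 432 and 837 in full lists as well.

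Taking equal replicate numbers as pairs (replicate block), regions gained in at least 2 pairs and lost in none numbered 1829, 2261, 1675, 1219, 2678 and 2686. Without the pairing, regions with at least 2 more libraries gave the same counts, as they must by construction, so the block moved no count. The labels do not say that the numbers pair the libraries, and no correlation reached 0.1: deviations of libraries with the same number correlated by -0.0104 to 0.0545 (mean 0.0225), and those with different numbers by -0.0112 on average. The mean of the same numbers was the highest of 36 arrangements of the numbers (exact permutation, one-sided, p = 0.0278, a test added after seeing the data), and 4 of 9 libraries correlated best with their own number in both other groups. This is a weak hint from the data that the numbers carry something shared. In the sample titles the number stands on the cell name, before the treatment, so treated and untreated Tex libraries of equal number may be pairs. The titles do not state this. Under the block the near-boundary difference of 5.53 percentage points had an exact permutation p of 0.111, past no threshold, while similarity within groups (exact permutation p = 0.0278) and the number of gene lists past the threshold (0) kept their calls. In runs added after seeing the data, the peak number per library kept its call under the block (exact permutation p = 0.0278) and the covered length did not (exact permutation p = 0.0556). The block leaves fewer labellings, with 0.0278 as the smallest p. The shares in libraries left out, the held-out comparison, the single genes and the Fisher tests were not run under it. The shared regions of both comparisons with Tex DMSO numbered 269 and 520, with the pairing and, in a run added after seeing the data, without it, so their rise over 25 and 60 comes from the looser count and not from the block.

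Similarity within groups stayed past the threshold under every alternative run, with 0.0637 to 0.120 on leaving out 1 library. The near-boundary share, Tex minus Tact, kept its sign, at 5.04 to 6.27 points on leaving out 1 library, with exact permutation p from 0.0214 to 0.104; the cause was not tested. It was 12.6 points with all deposited peaks and 15.4 with the stricter q (both exact permutation p = 0.00357), and 7.87 when ranked by fold (exact permutation p = 0.00714). The lists with all deposited peaks and with the stricter q differ in length, so their larger values cannot be told apart from list length. The number of gene lists past the threshold was 0 at equal length and on leaving out any library, 3 when ranked by fold, 14 with all deposited peaks and 13 with the stricter q, where it follows the lengths of the lists. The held-out difference was 13.4 and 14.3 points with all deposited peaks and the stricter q, -1.27 when ranked by fold, -6.76 to -3.91 on leaving out 1 library and -2.86 at the next shortest length without Tex DMSO 3. Its mirror (share of Tex DMSO regions called in Tex Mezi minus held-out Tex DMSO), planned but with alternatives added after seeing the data, was -0.719 at equal length, 22.4 with all deposited peaks, 22.6 with the stricter q, -6.79 when ranked by fold, 0.0597 with fixed windows and -3.45 to 3.01 on leaving out 1 library. Regions shared by both comparisons with Tex DMSO numbered 601 and 2 with all deposited peaks, 510 and 0 with the stricter q, 40 absent when ranked by fold, and 32 to 72 absent and 66 to 161 present on leaving out 1 library. Of 47 named regions, 41 kept the full separation of the groups when ranked by fold (not those at OASL, S1PR1, CBLB, IKZF1, SRGN and the IL1R1 region outside the gene) and 46 with the stricter q (not SORCS1), and 0 turned. These regions were chosen for having no peak in any full list of the other group, so the choice all but excluded a turn. The motif comparison and its alternatives were not run.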

Other observations

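Several genes had more peaks in Tex Mezi than in Tex DMSO without overlap between libraries of the equal-length lists. PMAIP1, a pro-apoptotic gene, had 6 ± 1 peaks in Tex Mezi and 1.67 ± 0.577 in Tex DMSO, NRP2, a semaphorin receptor, 4.33 ± 0.577 and 1.33 ± 0.577, SMOX, a polyamine oxidase, 4 ± 0 and 1 ± 1.73, and S1PR1 5.33 ± 1.15 and 3 ± 0 (SD, n = 3). ARID1B, a chromatin remodelling subunit, had 2 ± 0 and 7 ± 1, and SETD2, a histone methyltransferase, 0 and 3 ± 1. NRP2 and SMOX had 0 peaks in every Tact DMSO list of equal length, while ARID1B had 8.33 ± 1.15 there. Chance gives non-overlap in 10% of genes for 3 against 3 without ties. The counts were 212 higher and 152 lower of 12071 genes with a peak, below that share. Peak numbers per gene are small whole numbers, and ties lower the share that chance gives by an amount not determined here. The comparison with 10% therefore cannot decide, and non-overlap by itself was not shown to set these genes apart from chance. They were chosen after their values were seen.

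Between Tex DMSO and Tact DMSO, in the equal-length lists again, PDE4B, a cyclic AMP phosphodiesterase, had 5.67 ± 1.15 peaks against 11.7 ± 1.53, MGAT5, a glycosylation enzyme, 0 against 4.67 ± 1.15, and RPTOR, a subunit of an mTOR complex, 1.67 ± 0.577 against 5 ± 0 (SD, n = 3). PIP5K1B, MTSS1 and ST3GAL1 had more peaks in Tex DMSO, with 4.67 ± 1.15 against 1.33 ± 0.577, 3 ± 1 against 0, and 4.33 ± 1.15 against 1.33 ± 0.577. In this pair 240 genes were higher and 326 lower of 12248, and in Tex Mezi against Tact DMSO 477 and 494 of 12086. CD28 had 0.333 ± 0.577 peaks in Tex Mezi and 4.67 ± 1.53 in Tact DMSO at equal length, and 7.67 ± 2.31 and 13 ± 4 in the full lists. The order of the means turned in the full lists, which differ in length, for PIP5K1B (7 ± 1.73 in Tex DMSO and 9 ± 2 in Tact DMSO), MTSS1 (4.67 ± 1.15 and 9 ± 4) and ST3GAL1 (6.33 ± 1.53 and 13.3 ± 3.51), and for ARID1B between Tex Mezi and Tex DMSO (14.3 ± 1.53 and 9.67 ± 2.52; SD, n = 3).

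The splits of the libraries, the shared regions and the held-out comparison were planned. How their outcomes would be read, and the other tests of explanations here, were set after the results were seen. For regions of one group alone, the real split gave 1040 regions for Tex DMSO against Tact DMSO (highest other split 213), 641 for Tex Mezi against Tex DMSO (209) and 1846 for Tex Mezi against Tact DMSO (143), and in each case 1 of the 10 splits of the 6 libraries, the real one, gave as many. With 10 splits a share under 0.05 is out of reach. The comparisons that share Tex DMSO had 25 regions absent from Tex DMSO in common. Simulated unchanged groups, with the calls of each region permuted over the 9 libraries, gave 14.8 ± 4.10 (SD, 100 draws, highest 27). Independent lists, drawn from all 23938 regions, gave 11.03. The same comparisons had 60 regions present in Tex DMSO in common, where simulation gave 26.8 ± 5.32 (highest 40) and independent lists 3.83. The number was 61 with fixed windows around summits. With 3 libraries the shared group cannot be split, so part of any excess may come from it. Permuting each region by itself also removes what the regions of a library share, so the simulated spread may be too narrow. Independent lists leave out the shared group altogether.

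The first pattern is the low number of peaks in Tex DMSO. Per unit of recovered background, the highest Tex DMSO library had 16133 peaks and the lowest Tact DMSO library 22216. That ratio takes peak number as proportional to background, which was not shown, so it does not decide by itself. Tex DMSO 2 and Tex DMSO 3 had backgrounds of 1.691 and 1.488, not below the highest of Tact DMSO, 1.484. They had 25582 and 12828 peaks, against at least 32968 in Tact DMSO. For these libraries a lower depth than in Tact DMSO as the whole cause was argued against. Tex DMSO 1 had a background of 1.197, below every Tact DMSO library, so for it depth stays open. Against Tex Mezi the same 16133 lies above the lowest value of that group, 12824, so this ratio cannot decide. Tex Mezi 1 and Tex Mezi 3 had backgrounds of 1.424 and 1.684, with 30798 and 30524 peaks. Tex DMSO 2 had 25582 peaks at a higher background, 1.691. Tex DMSO 3 had 12828 peaks at 1.488, above the background of Tex Mezi 1. For Tex DMSO 2 and Tex DMSO 3, these values argue against a lower depth as the whole cause. Tex DMSO 1 had a lower background than every Tex Mezi library, so for it depth and treatment cannot be told apart. A lower sensitivity in Tex DMSO, by which the weakest regions are missed first, was not decided: 4.42% of 5900 regions of Tact DMSO missing in the full Tex DMSO lists were among the strongest peaks, against 35.3% of all Tact DMSO regions, and 7.45% against 46.4% for Tex Mezi, but choosing regions by their absence leaves out the strong shared ones whatever the cause. It stays open, as do fewer open regions in Tex DMSO cells and a difference in sample quality, which were not tested.

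The second pattern is that regions of Tex libraries alone lay near gene boundaries more often (40.7% and 28.8%) than those of Tact DMSO alone (6.03% and 6.02%), where all regions gave 37.7%. For a shift of rank within the Tact DMSO lists, in place of a missing peak, 98.0% of the near-boundary regions of Tex Mezi had a peak in at least 1 full Tact DMSO list, against 82.5% of regions farther away, and for Tex DMSO 100% and 95.3%. Most directions without the pattern had such an excess as well. It was 88.9% against 48.4% for Tex Mezi regions missing in Tex DMSO. For Tact DMSO regions missing in Tex DMSO and in Tex Mezi it was 64.1% against 59.4% and 79.7% against 74.8%. Tex DMSO regions missing in Tex Mezi had none, with 100% for both, which is the ceiling. The excess is thus not particular to this pattern, the values of Tex DMSO are close to the ceiling, and a shift of rank stays open. So does a biological difference in openness at gene boundaries, which was not tested.

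The third pattern is that Tex DMSO 2 shared more base pairs with Tex Mezi (Jaccard index 0.585) than with its own group (0.496). A mislabelled library was argued against: regions of Tex Mezi chosen without it were called in at most 31.5% of cases in Tex DMSO 2, and in at least 58.7% in a held-out Tex Mezi library. Peak width may account for most of it, since the excess of 0.0883 fell to 0.00469 with windows of fixed width.

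A hypothesis from the title of the series, that mezigdomide brings back Tact DMSO regions in Tex cells, was tested with the held-out libraries. The difference was -5.60 percentage points at equal length and 13.4 with all deposited peaks, so the direction rested on the length of the lists, and the data did not decide. At equal length it stayed negative when ranked by fold (-1.27) and on leaving out 1 library (-6.76 to -3.91). With all deposited peaks the mirror, for Tex DMSO regions, was 22.4, so a gain there was not particular to Tact DMSO regions. Mean similarity to Tact DMSO was 0.492 for Tex Mezi and 0.469 for Tex DMSO libraries in base pairs (exact permutation, two-sided, p = 0.7), and 0.515 and 0.535 in windows of fixed width (exact permutation p = 0.4).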
